A study of Mus musculus with 10 samples.

How the data were processed

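The samples were GFP-positive cells sorted from the proximal jejunum of mice with a GFP reporter in the Lgr5 locus, after intravenous adenovirus carrying Fc (control), the extracellular domain of LGR5 or Rspo1. The values were FPKM made by the authors and deposited as 1 table of 24510 rows with 8 libraries. Per the submitters' processing notes, TopHat, HTSeq, DESeq2, Cufflinks and the mouse build mm9 were used; their versions, roles, the annotation and the strand setting are not given in the sources used here. The table named genes by symbol only. The reference annotation at hand was of another build, so no coordinates are given, and 95.2% of the symbols were found in its table of gene names. Transcript lengths, used for a length check only, were medians over the protein-coding transcripts of GENCODE M21.

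Columns of the treated groups matched single sample titles. The 2 control columns carried a name that gives neither the sort nor the sample, and they were assigned to the GFP-positive Fc group because the series describes 2 such replicates. The 2 GFP-negative Fc samples were not analysed here. The planned comparison of GFP-positive with GFP-negative control cells and the planned test of a sort signature were therefore not run. The plan assumed 10 libraries in 4 groups; the fit used 8 libraries in 3 groups, with 5 residual degrees of freedom.

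From the table, 27 rows with a date in place of a symbol were left out and 391 identical repeated rows were dropped. The values of 89 symbols on several differing rows were summed, which left 23969 symbols. Genes with FPKM of at least 1 in at least 2 libraries were kept, 11454 in all. The log2(FPKM + 1) values, as deposited and without further scaling, were fitted with limma 3.58.1 (lmFit, contrasts, eBayes with trend) in R 4.3.3 over all 8 libraries, with group means and no covariate. Tests were two-sided, and p-values were Benjamini-Hochberg adjusted over all genes tested, with a threshold of 0.05. SE is the moderated standard error of a log2 change. Tables and figures were made with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

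Before the data were examined, 24 gene lists, the design, the alternatives and the rule for named genes were fixed. The lists held Wnt targets, R-spondin and Wnt receptors, crypt base and reserve stem cell markers, markers of Paneth, goblet, enteroendocrine, tuft and enterocyte cells, and Notch, cell cycle, ribosome biogenesis, ribosomal protein, interferon, MHC class II, immediate early, p53, cholesterol, fatty acid oxidation, unfolded protein response, immune, mesenchymal, epithelial and mitochondrially encoded genes. Some genes were on more than 1 list. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. With an estimated correlation camera also bases its test on the 5 residual degrees of freedom, which weakens it further. For each comparison the rule named up to 8 genes with the largest rise and 8 with the largest fall among called genes with a mean FPKM of at least 5 in the higher group and no overlap between groups. It left out predicted genes and the Snor, Mir, Rn and Scarna families of non-coding RNA, and added up to 4 called members of each list with the smallest p and a set of key genes whatever their p. The goblet list gave 2 symbols for 1 gene, Clca1 and Clca3, and both were in the table. Clca3 was used because the other Clca names in the table were older ones; this choice was made after the values had been seen, and the result with Clca1 is given with the alternatives. Some genes named by this rule are not reported here.

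The steps were tested on simulated data with the fitted spread of the 11454 genes, of which 200 were changed. Of changes of 1 on the log2 scale, 22% were recovered for Rspo1 against Fc, 24% for LGR5-ECD against Fc and 29% for Rspo1 against LGR5-ECD. Of changes of 2, the shares were 97%, 94% and 96%, and false calls numbered 5, 8 and 4. The noise was drawn separately for each gene and library, without shifts common to several genes. The shares and false calls hold only for such data and may be too favourable for the real libraries. Both comparisons with the control share its libraries, so their covariance was set beside that of 100 simulations of unchanged groups, and their shared calls beside those of 20 simulations put through the whole fit. After these values were seen, the covariance was also computed with 1 control for each comparison and simulated on the other scales. Relative depth was estimated from the ratios of values under 0.3 FPKM between libraries. Between 25.7% and 35.3% of these ratios lay on steps of whole reads within 0.04 on the log2 scale, against 20% by chance, so whole reads were not recovered and no count test was run. The depth values are rough for that reason.

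The alternatives were another pseudocount, no filter or a filter at 5 FPKM, median-ratio scaling, quantile normalization, a fit of only the groups compared, robust eBayes without trend, a replicate block, the highest row kept for repeated symbols, and each library left out in turn. In a comparison with 1 control left, the lone library was assumed to vary like the other groups. The values gave no sign that the replicate numbers pair Rspo1 and LGR5-ECD libraries, as given with the alternatives.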

Results

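Transcripts were measured by bulk RNA sequencing in epithelial cells of the mouse proximal jejunum. The mice carried a GFP reporter in the locus of Lgr5, a receptor for R-spondins that marks the stem cells at the crypt base, and the libraries came from cells sorted as GFP-positive. Before the harvest each mouse had received an adenovirus by intravenous injection. One virus carried Rspo1, a secreted protein that strengthens Wnt signalling (R-spondin gain of function), one carried the extracellular domain of LGR5 (LGR5-ECD, labelled as R-spondin loss of function), and the control virus carried Fc. The series text calls the samples biological replicates. The table analysed here held 8 libraries, with 3 Rspo1, 3 LGR5-ECD and 2 control libraries, and 11454 genes passed the filter on low values. The control columns name neither the sort nor the sample, and they were read as the GFP-positive Fc cells from the wording of the series. Every comparison with the control rests on that reading. Another 2 control samples, of GFP-negative cells, were not analysed here.

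The values were FPKM, fragments scaled by transcript length and library total, so read totals were unknown. FPKM summed to between 189335 and 275937 per library. Steps between the values of low genes placed the depth of LGR5-ECD replicate 3 at 0.52 times that of control 1, the other LGR5-ECD libraries at 1.46 and 2.35 times, control 2 at 1.08 times and the Rspo1 libraries at 1.96 to 2.3 times. LGR5-ECD replicate 3 had 11485 genes above 0, against 13417 to 14197 in the other 7 libraries. Across genes, the mean correlation of a library with the others of its group was 0.962 to 0.965 for Rspo1, 0.909 to 0.936 for LGR5-ECD and 0.921 between the controls. Control 1 also had a mean of 0.921 with the libraries of the other groups, and was closer to 2 LGR5-ECD libraries (0.937 and 0.927) and to all 3 Rspo1 libraries (0.927 to 0.935) than to control 2. Rspo1 itself was listed at 0 FPKM in each of the 8 libraries. All log2 changes below are on the log2(FPKM + 1) scale, which understates the change of low genes.

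The first comparison asked how GFP-positive cells exposed to R-spondin gain of function differed from those exposed to loss of function. Crypt base stem cell genes were far higher in Rspo1 than in LGR5-ECD cells. Lgr5, whose locus also drives the GFP used for the sort, stood at 103.1 ± 8.53 FPKM in Rspo1 (SD, n = 3) and 5.14 ± 2.84 FPKM in LGR5-ECD (SD, n = 3), a log2 change of 4.18 (SE 0.32, adjusted p = 0.000113). Olfm4, a secreted stem cell marker, was at 1391 ± 74.7 and 113.5 ± 119.1 FPKM (SD, n = 3 each), and Ascl2, a Wnt-driven transcription factor of these cells, at 35.3 ± 5.09 and 2.92 ± 2.55 FPKM. Enterocyte genes went the other way. Krt20, a keratin of differentiated cells, was at 4.36 ± 0.336 FPKM in Rspo1 and 38.2 ± 2.33 FPKM in LGR5-ECD (log2 change -2.87, SE 0.18, adjusted p = 5.85e-05).

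**Figure D1:**
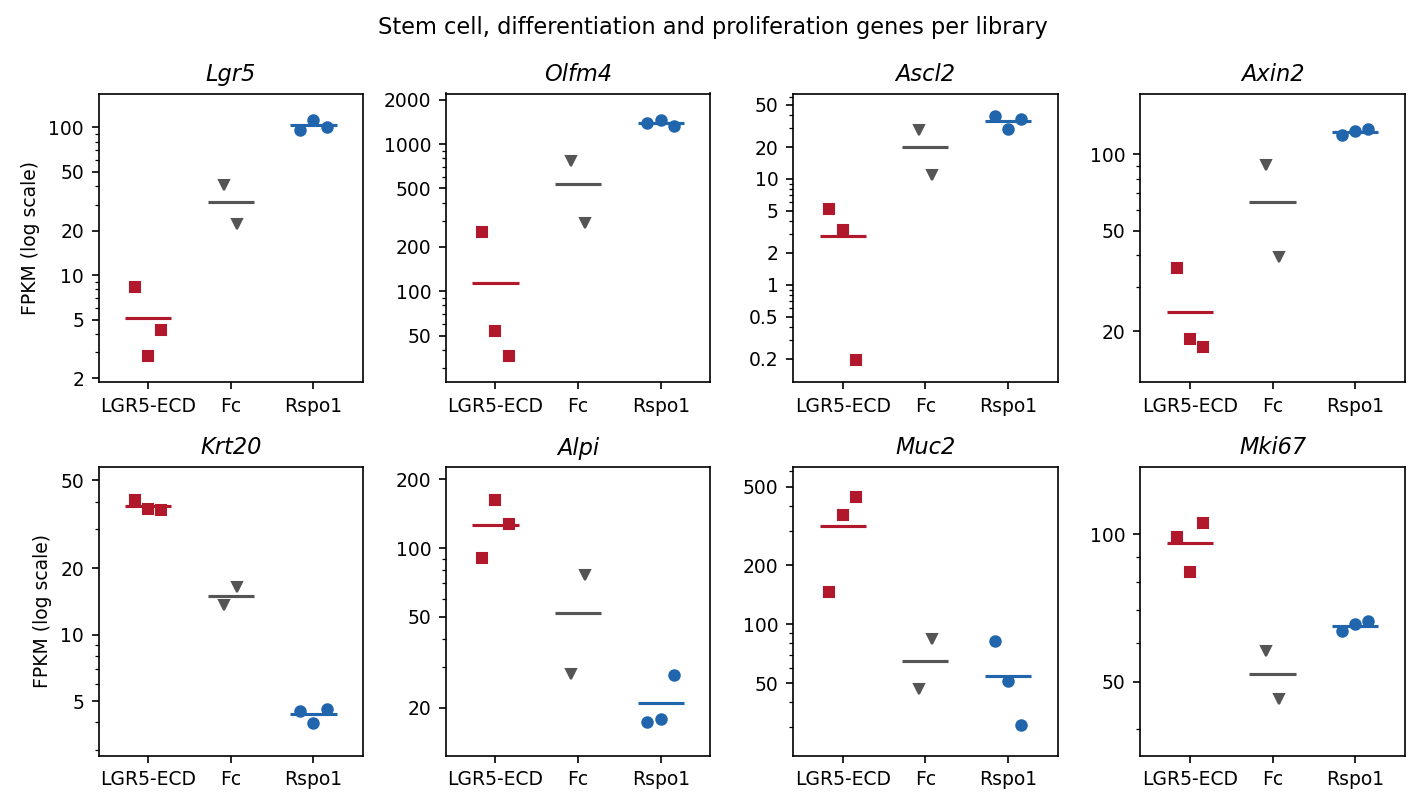
FPKM of 8 genes in each library on a logarithmic axis, grouped as LGR5-ECD (squares, n = 3), Fc (triangles, n = 2) and Rspo1 (circles, n = 3); horizontal bars are group means. For Lgr5, Olfm4, Ascl2 and Axin2 every Rspo1 library lies above every LGR5-ECD library, and for Krt20, Alpi and Muc2 every Rspo1 library lies below; Lgr5 ranges from 2.84 to 8.31 FPKM in LGR5-ECD and from 96.4 to 112.7 FPKM in Rspo1.

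In this comparison 563 genes were higher and 405 lower in Rspo1, of which 441 and 319 changed at least 2-fold. Among the genes with the largest rises were Pgc, which encodes a pepsinogen (log2 change 4.66, SE 0.40), Gkn3 (4.62, SE 0.62), Ccdc3 (4.37, SE 0.40), Slc14a1 (3.77, SE 0.39), Phlda1 (3.74, SE 0.29) and Pla2g2a (3.71, SE 0.48). Among the largest falls were Clca3, a secreted goblet cell protein (-3.82, SE 0.73), Naaladl1 (-3.67, SE 0.28), Car4, a carbonic anhydrase (-3.65, SE 0.45), Slc51a, a bile acid exporter subunit (-3.48, SE 0.37), Cox7a1 (-3.24, SE 0.49), St3gal4 (-3.18, SE 0.19) and Slc6a20a (-3.16, SE 0.27). Adjusted p-values of these genes ran from 5.85e-05 for St3gal4 to 0.0102 for Clca3.

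Of 30 crypt base stem cell markers tested, 26 rose and 0 fell (28 and 0 adjusted over the list alone), with a median log2 change of 2.45. The camera set test gave adjusted p = 4.62e-27, and adjusted p = 0.135 with an estimated correlation. Phlda1, Soat1 (3.12, SE 0.31) and Cyp2e1 (2.56, SE 0.26) were among them. Of 25 Wnt target genes, 19 rose and 0 fell (20 and 0 adjusted over the list alone; median 1.63). The Wnt list shares genes with the stem cell list, Lgr5, Ascl2, Axin2, Rnf43 and Znrf3 among them, so their rises are not separate evidence. For the Wnt targets the set test gave adjusted p = 1.56e-16, and adjusted p = 0.135 with an estimated correlation. The Wnt targets that rose included the Wnt antagonist Nkd1 (3.25, SE 0.30), the receptor Ephb3 (3.06, SE 0.36), Cd44 (2.08, SE 0.21) and the feedback inhibitors Axin2 (2.38, SE 0.33), Rnf43 (1.62, SE 0.24) and Znrf3 (1.45, SE 0.25). Smoc2 also rose (1.10, SE 0.25, adjusted p = 0.0230). The list of R-spondin and Wnt receptor genes, which shares Lgr5, Rnf43 and Znrf3 with the lists above, had 6 of 18 members up and 1 down (7 and 1 adjusted over the list alone), with Fzd7 (2.04, SE 0.32) and Fzd2 (1.84, SE 0.31) among the rises. For the receptor genes the set test gave adjusted p = 0.000434, and adjusted p = 0.318 with an estimated correlation. Of 17 Notch and secretory commitment genes, 7 rose and 1 fell (9 and 1 adjusted over the list alone), including Sox4 (2.38, SE 0.22), Hes6 (1.40, SE 0.22), Lfng (1.68, SE 0.31) and the Notch effector Hes1 (0.98, SE 0.18). For the Notch genes the set test gave adjusted p = 0.00813, and adjusted p = 0.318 with an estimated correlation. Among 9 reserve or +4 stem cell markers 5 rose and 2 fell (5 and 2 adjusted over the list alone). Mex3a rose by 2.12 (SE 0.26) and Sox9 by 2.00 (SE 0.25), and both are also on the crypt base list. Ly6a, an interferon-inducible surface protein, fell by 2.45. For the reserve markers the set test gave adjusted p = 0.0170, and adjusted p = 0.371 with an estimated correlation.

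Of 40 enterocyte markers, 28 fell and 0 rose (30 and 0 adjusted over the list alone), with a median of -1.24. For this list camera gave adjusted p = 3.73e-28, and this call held with an estimated correlation (adjusted p = 0.000895). Sis, the brush border sucrase-isomaltase, was at 3.93 ± 0.491 against 30.6 ± 4.86 FPKM (SD, n = 3 each). Alpi, the intestinal alkaline phosphatase, fell by 2.53 (SE 0.35), Npc1l1, the cholesterol transporter, by 2.48 (SE 0.19), Ace by 2.14 (SE 0.18) and Fabp1 by 2.05 (SE 0.33). Of 22 goblet cell markers, 8 fell and 1 rose (12 and 1 adjusted over the list alone). For the goblet markers the set test gave adjusted p = 1.09e-06, and adjusted p = 0.318 with an estimated correlation. The mucin gene Muc2 fell by 2.48 (SE 0.45), Ccl6 by 2.29 (SE 0.37) and Sytl2 by 1.51 (SE 0.28), and the transcription factor gene Foxa3 rose by 2.37 (SE 0.20). Paneth cell markers split, with 3 of 23 up and 2 down (3 and 3 adjusted over the list alone). For the Paneth markers the set test gave adjusted p = 0.319, and adjusted p = 0.782 with an estimated correlation. The 3 that rose were Pla2g2a, Fgfrl1 (2.72, SE 0.46) and Wnt3 (1.64, SE 0.37), the first of which is also on the stem cell list, and the defensin gene Defa22 was among those that fell (-2.55, SE 0.67). Lyz1, the lysozyme gene, stood at 714.7 ± 258.8 and 1310 ± 751.6 FPKM (SD, n = 3 each, adjusted p = 0.695) and Defa24 had adjusted p = 0.888. Among 24 tuft cell markers 1 rose and 2 fell (1 and 8 adjusted over the list alone), with a rise of Cd24a, which is also found on crypt base cells (0.96, SE 0.21), and Matk among the falls (-1.43, SE 0.39); Dclk1 did not pass (-1.36, SE 0.38, adjusted p = 0.0502). For the tuft markers the set test gave adjusted p = 1.86e-05, and adjusted p = 0.387 with an estimated correlation. Of 17 enteroendocrine markers 1 rose and 0 fell (0 and 0 adjusted over the list alone; camera adjusted p = 0.790), and that 1 was Neurog3, the gene of the endocrine progenitor factor (1.33, SE 0.35). The list median of 0.07 was -0.03 after quantile normalization, and the set test pointed down. Chga (adjusted p = 0.355) and the secretory regulator Atoh1 (adjusted p = 0.617) did not pass.

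Interferon response genes, which cells use against viruses, were lower in Rspo1. Of 38 tested, 21 fell and 0 rose (27 and 0 adjusted over the list alone), with a median of -1.17. For the interferon list camera gave adjusted p = 3.26e-22, and adjusted p = 0.135 with an estimated correlation. Oas1a (-2.22, SE 0.19), Zbp1 (-1.84, SE 0.19), Oas2 (-2.32, SE 0.25) and Oas1g (-2.22, SE 0.31), which encode antiviral enzymes and a nucleic acid sensor, had the smallest p. Cytosolic ribosomal protein genes were higher, with 15 of 54 up and 0 down (46 and 1 adjusted over the list alone), a median of 0.75, camera adjusted p = 3.58e-16, and adjusted p = 0.3002 with an estimated correlation. Rpl7 (1.06, SE 0.20), Rps4x (1.02, SE 0.20), Rpl27a (0.84, SE 0.18) and Rpsa (0.98, SE 0.21) were among them. Processed copies of such genes can share their reads. Of 37 cell cycle genes only Rrm2 passed (-1.40, SE 0.28; 0 up and 1 down adjusted over the list alone), the list median was -0.26, and Mki67 had adjusted p = 0.0819 (log2 change -0.55, SE 0.17). For the cell cycle genes the set test gave adjusted p = 8.22e-05, and adjusted p = 0.371 with an estimated correlation. Among 22 immediate early and dissociation stress genes 3 rose (6 adjusted over the list alone), which were Cyr61 (2.44, SE 0.48), Btg2 (0.93, SE 0.20) and Nr4a1 (2.06, SE 0.51). For the immediate early genes the set test gave adjusted p = 0.00749, and adjusted p = 0.410 with an estimated correlation.

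Of 8 MHC class II genes 2 rose, Ciita (1.27, SE 0.26) and H2-Eb1 (0.81, SE 0.17), with camera adjusted p = 0.0206, and adjusted p = 0.401 with an estimated correlation. The cell cycle inhibitor Cdkn1a fell by 2.37 (SE 0.25) among 19 p53 target and apoptosis genes, where Btg2 and Sesn2 (1.27, SE 0.28) rose and camera gave adjusted p = 0.568. For 24 cholesterol synthesis genes the set test gave adjusted p = 2.66e-05, and adjusted p = 0.318 with an estimated correlation. Among 25 fatty acid oxidation and ketogenesis genes 2 fell, Ppara among them (-1.64, SE 0.31), as did the chaperone genes Hsp90b1 (-0.81, SE 0.17) and Pdia6 (-0.78, SE 0.20) among 21 unfolded protein response genes. For the fatty acid genes the set test gave adjusted p = 0.00813, and adjusted p = 0.488 with an estimated correlation. For the unfolded protein list the set test gave adjusted p = 6.86e-05, and adjusted p = 0.186 with an estimated correlation. Over these 5 lists, the counts adjusted over the list alone were 2, 2, 0, 0 and 0 up and 0, 1, 0, 1 and 2 down, in the order given. Among 16 epithelial identity genes Krt18 rose (1.21, SE 0.24) and Lgals4 (-0.97, SE 0.21) and Krt19 (-1.06, SE 0.26) fell (1 up and 3 down adjusted over the list alone; camera adjusted p = 0.118), and 0 of 27 ribosome biogenesis genes passed (0 adjusted over the list alone; camera adjusted p = 0.389). Markers of immune cells (4 of 30 tested) and of mesenchymal, endothelial, neural and red cells (2 of 27 tested) gave 0 calls in each of the 3 comparisons and were too few for a set test. Adjusted over the list alone, 1 immune marker was higher in each treated group than in the control. The mitochondrially encoded genes had 0 members in the table's tested genes.

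**Figure D2:**
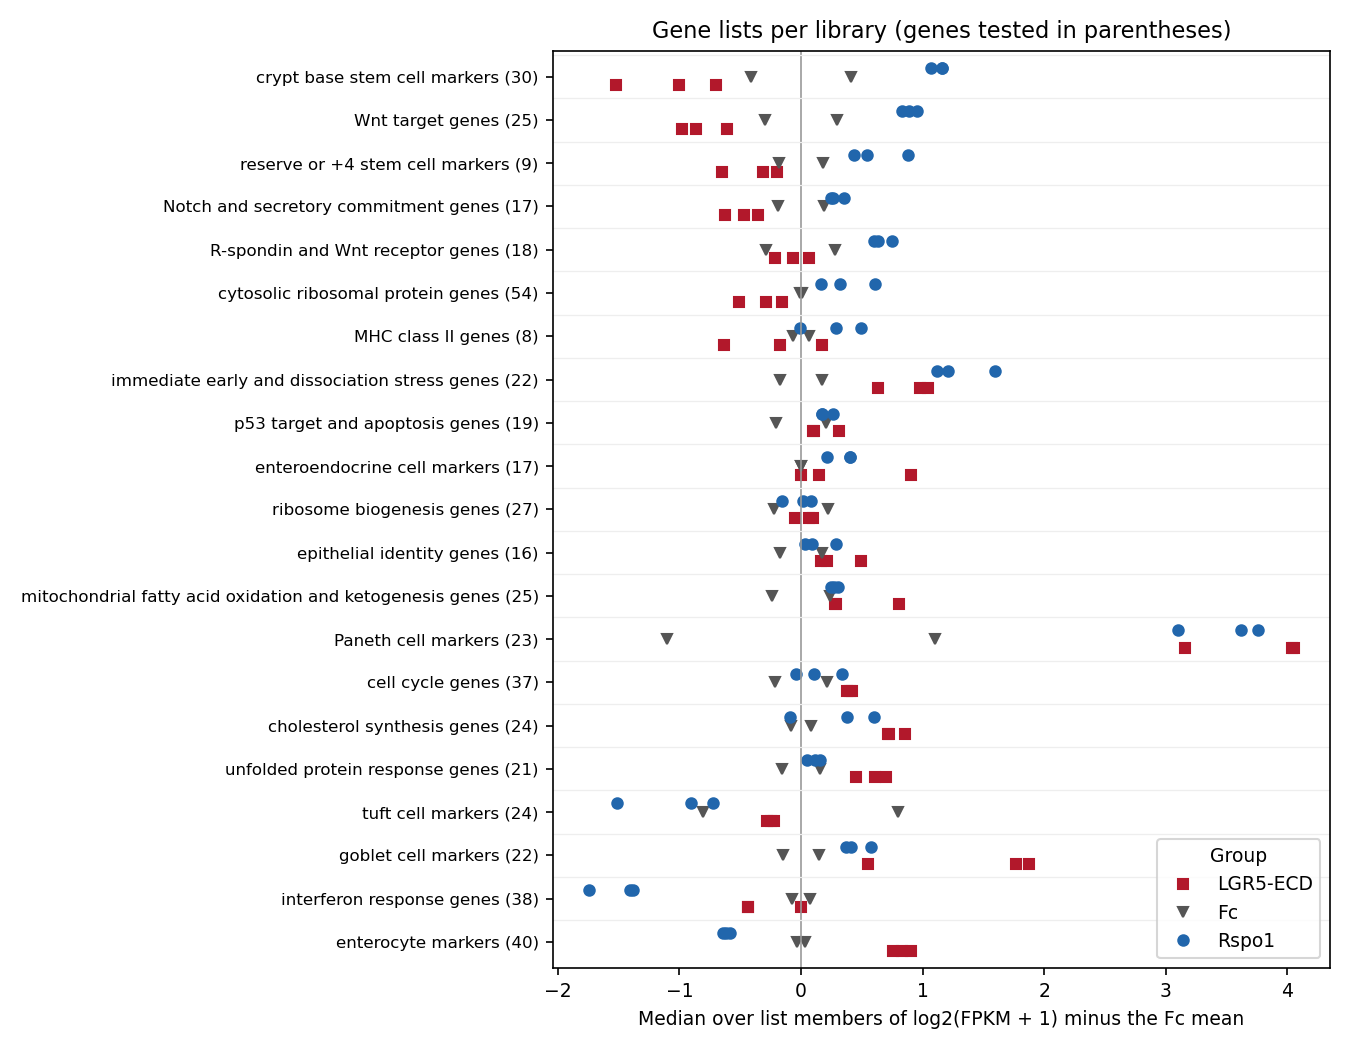
Median over the tested members of each fixed gene list of log2(FPKM + 1) minus the Fc mean of the gene, 1 point per library (squares LGR5-ECD, triangles Fc, circles Rspo1), with lists ordered by the difference between the treated groups. Rspo1 libraries lie at 1.07 to 1.16 and LGR5-ECD libraries at -1.52 to -0.70 for crypt base stem cell markers, and all 6 treated libraries lie at 3.10 to 4.06 for Paneth cell markers, with the 2 controls at -1.10 and 1.10.

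The number of calls depended on the libraries. Without Rspo1 replicate 1, 2 or 3 it was 311, 231 or 212 higher and 241, 183 or 218 lower, and without LGR5-ECD replicate 2 the lower count was 269. Over the fits without 1 library, 2 to 10 ribosomal protein genes, 22 to 26 stem cell markers and 17 to 19 Wnt targets rose, and 12 to 21 interferon genes, 4 to 11 goblet markers and 19 to 28 enterocyte markers fell. Of 77 named calls, 53 kept an adjusted p under 0.05 without each library in turn, Lgr5, Olfm4, Ascl2, Krt20 and Sis among them. In the set tests 4 calls were lost, for the Notch and immediate early lists without LGR5-ECD replicate 1 (adjusted p = 0.0717 and 0.171), MHC class II genes without Rspo1 replicate 1 (0.125) and fatty acid oxidation genes without LGR5-ECD replicate 2 (0.242).

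The second comparison asked what R-spondin gain of function changed relative to the control virus. Interferon response genes were lower in Rspo1 than in the control. Oas2 was at 1.06 ± 0.338 FPKM in Rspo1 (SD, n = 3) and 24.7 ± 7.94 FPKM in the control (SD, n = 2; log2 change -3.62, SE 0.28, adjusted p = 0.00104). Irf7, the gene of a transcription factor that amplifies the interferon response, was at 10.1 ± 4.54 and 81.7 ± 4.55 FPKM, and Isg15 was listed at 0 in all 3 Rspo1 libraries against 6.44 and 11.2 FPKM in the controls. Lgr5 rose (1.75, SE 0.36, adjusted p = 0.0470), as did Rnase1, a secreted ribonuclease (3.66, SE 0.37, adjusted p = 0.00335).

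In total 77 genes were higher and 66 lower in Rspo1 than in the control, a share of 53.8% higher. The share was 40.6% with median-ratio scaling (86 and 126 genes) and 41% with quantile normalization (120 and 173). The median of all genes as deposited was shifted by 0.16, against 0.01 under either scaling. Rises and falls are ranked here among the genes that the naming rule kept, which leaves out predicted genes. The largest rises, besides Rnase1, were in the antimicrobial genes Defa3 (4.68, SE 0.87), Defa26 (4.13, SE 0.58), Defa22 (3.65, SE 0.75), Pla2g2a (3.64, SE 0.54) and Ang4 (3.60, SE 0.63), in Reg4 (3.56, SE 0.58) and in the non-coding RNA gene Rmrp (3.36, SE 0.48). The largest falls, besides Oas2, Isg15 and Irf7 (-2.97, SE 0.37), were in Ifit1 (-3.10, SE 0.33), Apol9b (-2.99, SE 0.43), Apol9a (-2.76, SE 0.33), Oas1g (-2.73, SE 0.35) and Fabp6, the ileal bile acid binding protein gene (-2.89, SE 0.51). Defensin genes are close copies of each other, so the split of reads among them is uncertain.

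Of 38 interferon response genes 16 fell and 0 rose (31 and 0 adjusted over the list alone), all 38 had a negative log2 change, and the median was -1.58. For this list the set test gave adjusted p = 5.69e-42, a call that held with an estimated correlation (adjusted p = 0.0375). Oas1a fell by 2.44 (SE 0.22) and Zbp1 by 1.87 (SE 0.22). Of 30 crypt base stem cell markers 4 rose and 0 fell (21 and 0 adjusted over the list alone; median 1.09), namely Lgr5, Phlda1 (2.04, SE 0.33), Pla2g2a and Tnfrsf19 (2.48, SE 0.50). For the stem cell markers the set test gave adjusted p = 3.54e-13, and adjusted p = 0.343 with an estimated correlation. Of 25 Wnt target genes 4 rose and 0 fell (15 and 1 adjusted over the list alone), with Cd44 (1.37, SE 0.24) and Nkd1 (1.91, SE 0.33) beside Lgr5 and Tnfrsf19. For the Wnt targets the set test gave adjusted p = 8.03e-07, and adjusted p = 0.343 with an estimated correlation. Ascl2 (0.93, adjusted p = 0.458), Olfm4 (1.55, adjusted p = 0.276), Smoc2 (1.00, adjusted p = 0.109), Axin2 (1.03, adjusted p = 0.192), Rnf43 (0.48, adjusted p = 0.398) and Znrf3 (1.02, adjusted p = 0.1002) did not pass. Only Lgr5 rose among 18 R-spondin and Wnt receptor genes (9 adjusted over the list alone). For the receptor genes the set test gave adjusted p = 0.00234, and adjusted p = 0.503 with an estimated correlation.

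Enterocyte markers fell, with 4 of 40 down and 0 up (13 and 0 adjusted over the list alone; median -0.65; camera adjusted p = 1.20e-12, held with an estimated correlation at adjusted p = 0.00717). These were Npc1l1 (-1.77, SE 0.22), Krt20 (-1.57, SE 0.20), Ace (-1.10, SE 0.20) and Apoa1 (-1.64, SE 0.30), and Alpi (adjusted p = 0.183) and Fabp1 (adjusted p = 0.279) did not pass. Paneth cell markers rose, with 9 of 23 up and 0 down (22 and 0 adjusted over the list alone; median 3.51), including Mmp7 (2.77, SE 0.31) and Mptx2 (3.13, SE 0.51). For the Paneth markers the set test gave adjusted p = 3.87e-18, and adjusted p = 0.196 with an estimated correlation. Beside this stands the spread of the controls: Lyz1 was at 184.3 FPKM in control 1 and 5.95 FPKM in control 2. In all, 21 of 23 Paneth markers were higher in control 1, with a median log2 difference of 2.21. Tuft cell markers were lower in control 1 than in control 2 for 24 of 24 genes (median log2 difference -1.60). In Rspo1 against both controls they had a median of -1.14, and Cd24a alone passed, upward (1.32, SE 0.24; 1 up and 4 down adjusted over the list alone). The median was -0.28 without control 2 and -1.93 without control 1, where 10 tuft markers fell. For the tuft markers the set test gave adjusted p = 2.63e-11, and adjusted p = 0.343 with an estimated correlation. Goblet cell markers gave 3 rises, Foxa3 (1.32, SE 0.23), Spink4 (2.46, SE 0.43) and Ccl9 (1.76, SE 0.33), among 22 (4 up and 1 down adjusted over the list alone; camera adjusted p = 0.399). Reg4 was the only rise among 17 enteroendocrine markers (3 up and 1 down adjusted over the list alone; camera adjusted p = 0.276).

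Immediate early genes, which respond within minutes to stimulation and tissue handling, also rose, with 9 of 22 up and 0 down (16 and 0 adjusted over the list alone). For the immediate early genes the set test gave adjusted p = 1.41e-12, and adjusted p = 0.196 with an estimated correlation. Jun (1.76, SE 0.26), Egr1 (2.70, SE 0.42), Fos (2.63, SE 0.41) and Atf3 (2.88, SE 0.41) had the smallest p. Rn45s, the ribosomal RNA precursor, named after its values were seen, was at 4418 to 5661 FPKM in Rspo1, 3317 to 4289 in LGR5-ECD and 1566 and 2006 in the controls. Cdkn1a fell (-1.59, SE 0.28) and Btg2 rose (1.11, SE 0.22) among 19 p53 target and apoptosis genes (2 up and 1 down adjusted over the list alone; camera adjusted p = 0.913). Ly6a fell (-2.33, SE 0.43) among 9 reserve or +4 stem cell markers (5 up and 1 down adjusted over the list alone; camera adjusted p = 0.196). Among 54 ribosomal protein genes 0 passed (0 adjusted over the list alone). For this list the set test gave adjusted p = 0.000141, and adjusted p = 0.703 with an estimated correlation, and the median of 0.38 was -0.02 after quantile normalization. The cell cycle, ribosome biogenesis, Notch, MHC class II, cholesterol synthesis, fatty acid oxidation, unfolded protein response and epithelial identity lists had 0 members past the threshold, also 0 adjusted over the list alone, and camera adjusted p from 0.2615 to 0.865; the medians of the unfolded protein response (0.05) and epithelial identity (0.13) lists were below 0 under both scalings. The set tests of the cell cycle and unfolded protein response lists pointed down although their medians were above 0. Mki67 (adjusted p = 0.410), Muc2 (0.795), Chga (0.0877), Dclk1 (0.308), Atoh1 (0.250), Lyz1 (0.0834) and Defa24 (0.115) did not pass.

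Counts of calls changed strongly with the libraries used. Without 1 Rspo1 library, 813 to 1179 genes were higher at an unadjusted limma p under 0.05, against 1372 with all libraries. Without control 1 there were 362 higher genes; without control 2, 11 higher and 13 lower; and without Rspo1 replicate 1, 2 or 3, 23, 8 or 12 higher and 28, 16 or 25 lower. Over these limma fits 0 to 14 stem cell markers, 0 to 10 Wnt targets, 0 to 6 receptor genes, 1 to 18 Paneth markers, 0 to 2 goblet markers and 1 to 6 immediate early genes rose, and 0 to 6 enterocyte markers and 5 to 10 interferon genes fell. The medians ran from 0.71 to 1.59 for stem cell and from 1.83 to 4.30 for Paneth markers, and the log2 change from 2.60 to 6.76 for Defa3, 2.14 to 5.07 for Ang4, 2.23 to 4.89 for Reg4, 1.46 to 3.50 for Tnfrsf19 and 2.07 to 4.18 for Mptx2. Of 40 named calls, 6 (Apol9a, Ifit1, Oas1a, Oas2, Rnase1 and Zbp1) kept an adjusted p under 0.05 without each library in turn. Lgr5 kept it only without control 1 (adjusted p up to 0.364, without control 2), Krt20 and Irf7 lost it without control 2 (0.0605 and 0.0746), and the set test of ribosomal protein genes was lost without control 1 (0.146).

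The third comparison asked what R-spondin loss of function changed relative to the control virus. Lgr5 fell from 31.3 ± 13.2 FPKM in the control (SD, n = 2) to 5.14 ± 2.84 FPKM in LGR5-ECD (SD, n = 3; log2 change -2.43, SE 0.36, adjusted p = 0.0250). Krt20 rose from 14.97 ± 2.00 to 38.2 ± 2.33 FPKM (1.30, SE 0.20, adjusted p = 0.0302) and Sis from 8.02 ± 1.98 to 30.6 ± 4.86 FPKM (1.82, SE 0.24, adjusted p = 0.0193). The defensin gene Defa22 (6.21, SE 0.75) and the chemokine gene Ccl6 (3.82, SE 0.42) rose as well.

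In all, 51 genes were higher and 31 lower, a share of 62.2% higher. The share was 48.4% with median-ratio scaling (46 and 49 genes) and 48.1% with quantile normalization (52 and 56). The ranking of rises and falls is again among the genes that the naming rule kept. Besides Defa22 and Ccl6, the largest rises were in Defa21 (5.67, SE 0.69), Defa2 (5.46, SE 0.78), Defa5 (4.63, SE 0.84), Ang4 (4.10, SE 0.63) and Mptx2 (3.82, SE 0.51), and in Cox7a1, which was listed at 0 in both controls and at 19.0 to 26.3 FPKM in LGR5-ECD. Besides Lgr5, the largest falls were in Pgc (-2.63, SE 0.45), Dmpk (-2.53, SE 0.40), Gramd1a (-2.42, SE 0.34), Slc14a1 (-2.40, SE 0.43), Ccdc3 (-2.39, SE 0.44), Kif12 (-2.23, SE 0.41) and Cpn1 (-2.23, SE 0.36), with adjusted p from 0.0201 to 0.0460.

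Of 30 crypt base stem cell markers 4 fell and 0 rose (18 and 0 adjusted over the list alone; median -1.15), namely Lgr5, Slc14a1, Cyp2e1 (-1.59, SE 0.29) and Phlda1 (-1.70, SE 0.33). For the stem cell markers the set test gave adjusted p = 4.40e-15, and adjusted p = 0.257 with an estimated correlation. Lgr5 was the only fall among 25 Wnt target genes (14 down and 0 up adjusted over the list alone) and among 18 R-spondin and Wnt receptor genes (2 down adjusted over the list alone; camera adjusted p = 0.213). For the Wnt targets the set test gave adjusted p = 1.82e-11, and adjusted p = 0.257 with an estimated correlation. Ascl2 (-2.57, SE 0.60, adjusted p = 0.0843), Olfm4 (-2.57, SE 0.67, adjusted p = 0.113), Axin2 (-1.36, adjusted p = 0.119), Rnf43 (-1.14, adjusted p = 0.0877), Znrf3 (-0.42, adjusted p = 0.469) and Smoc2 (-0.10, adjusted p = 0.883) did not pass. Of 40 enterocyte markers 4 rose and 0 fell (23 and 0 adjusted over the list alone; median 0.85; camera adjusted p = 3.68e-14, held with an estimated correlation at adjusted p = 0.00527). They were Sis, Krt20, Ace (1.04, SE 0.20) and the aminopeptidase gene Enpep (1.57, SE 0.30). Alpi (1.39, adjusted p = 0.139) and Fabp1 (1.21, adjusted p = 0.148) did not pass.

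Of 22 goblet cell markers 5 rose and 0 fell (10 and 1 adjusted over the list alone), with Ccl6, Sytl2 (1.99, SE 0.31), Guca2a, the gene of guanylin (2.49, SE 0.43), and Spink4 (2.35, SE 0.43) at the smallest p; Muc2 did not pass (2.17, SE 0.50, adjusted p = 0.0819). For the goblet markers the set test gave adjusted p = 1.56e-08, and adjusted p = 0.257 with an estimated correlation. Of 23 Paneth cell markers 9 rose and 0 fell (20 and 1 adjusted over the list alone), against controls that differed from each other as given above; Nupr1 rose by 2.88 (SE 0.37), and Lyz1 (adjusted p = 0.0703) and Defa24 (adjusted p = 0.116) did not pass. For the Paneth markers the set test gave adjusted p = 2.97e-17, and adjusted p = 0.257 with an estimated correlation. Reg4 (3.29, SE 0.58) and Chga, the endocrine granule protein gene (1.98, SE 0.37), rose among 17 enteroendocrine markers (4 up and 1 down adjusted over the list alone; camera adjusted p = 0.172). Tuft cell markers gave 0 calls (0 adjusted over the list alone; camera adjusted p = 0.0604), with Dclk1 at adjusted p = 0.601. The transcription factor gene Sox4 fell (-1.74, SE 0.25) among 17 Notch and secretory commitment genes (2 up and 4 down adjusted over the list alone), and Atoh1 had adjusted p = 0.146. For the Notch genes the set test gave adjusted p = 0.00683, and adjusted p = 0.310 with an estimated correlation.

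Immediate early genes rose here too, with 4 of 22 up and 0 down, namely Fos (2.80, SE 0.41), Egr1 (2.32, SE 0.42), Zfp36 (1.68, SE 0.30) and Atf3 (2.18, SE 0.41). In all, 11 rose adjusted over the list alone, and camera gave adjusted p = 3.96e-06, and adjusted p = 0.275 with an estimated correlation. Immediate early genes as a list and Rn45s were thus higher in both treated groups than in the controls. A difference in tissue handling between control and treated libraries would enter both comparisons with the control and was not tested. Interferon response genes had 0 calls among 38 (0 up and 3 down adjusted over the list alone), a median of -0.31, camera adjusted p = 2.31e-05, and adjusted p = 0.336 with an estimated correlation. The 37 cell cycle genes had 0 calls (4 up adjusted over the list alone), a median of 0.43, camera adjusted p = 0.000162, and adjusted p = 0.403 with an estimated correlation; Mki67 had adjusted p = 0.0736 (log2 change 0.88, SE 0.19). Another 6 lists had a set test past the threshold, no member called over all genes and no call with an estimated correlation. The 24 cholesterol synthesis genes had a median of 0.79 (8 up adjusted over the list alone), and the 21 unfolded protein response genes a median of 0.53 (3 up adjusted over the list alone). For the cholesterol genes the set test gave adjusted p = 5.56e-08, and adjusted p = 0.257 with an estimated correlation. For the unfolded protein list the set test gave adjusted p = 0.000124, and adjusted p = 0.257 with an estimated correlation. The 54 ribosomal protein genes had a median of -0.33 (0 adjusted over the list alone). For the ribosomal list the set test gave adjusted p = 1.56e-08, and adjusted p = 0.366 with an estimated correlation. For 25 fatty acid oxidation and ketogenesis genes the median was 0.33 (0 adjusted over the list alone), and for 16 epithelial identity genes 0.27 (0 adjusted over the list alone). For the fatty acid genes the set test gave adjusted p = 0.00298, and adjusted p = 0.447 with an estimated correlation. For the epithelial list the set test gave adjusted p = 0.0191, and adjusted p = 0.451 with an estimated correlation. The 9 reserve or +4 stem cell markers had a median of -0.39 (3 down adjusted over the list alone). For the reserve markers the set test gave adjusted p = 0.0437, and adjusted p = 0.420 with an estimated correlation. The ribosome biogenesis, MHC class II and p53 target lists had 0 calls, 0 adjusted over the list alone, and camera adjusted p of 0.797, 0.120 and 0.334. The first of these had a median above 0 that was below 0 under both scalings, and a set test that pointed down.

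These calls rest on control 2 and on LGR5-ECD replicate 2, and 0 of 33 named calls kept an adjusted p under 0.05 without each library in turn. Without control 2 limma called 0 genes in either direction (571 higher and 659 lower at an unadjusted p under 0.05), without LGR5-ECD replicate 2 it called 4 higher and 0 lower, and without control 1 it called 153 higher. It called 49 lower without LGR5-ECD replicate 1, and a fit of only these 2 groups called 4 and 0. At an unadjusted limma p under 0.05, 965 genes were higher and 885 lower without LGR5-ECD replicate 2, against 1184 and 752 with all libraries. Over the fits without 1 library 0 to 19 Paneth markers, 0 to 9 goblet markers, 0 to 5 enterocyte markers and 0 to 6 immediate early genes rose, and 0 to 9 stem cell markers and 0 to 4 Wnt targets fell. The log2 change ran from 2.79 to 6.46 for Defa5, 2.63 to 5.57 for Ang4 and 1.96 to 4.62 for Reg4. The medians ran from 0.17 to 0.64 for cell cycle, 0.10 to 0.55 for fatty acid oxidation, 0.08 to 0.48 for epithelial identity, -0.80 to -0.17 for reserve stem cell and -0.46 to -0.19 for interferon genes. Set test calls were lost for the reserve stem cell list without control 1 (adjusted p = 0.135) or LGR5-ECD replicate 1, the Notch list without LGR5-ECD replicate 1 (0.0942), and the fatty acid oxidation and epithelial identity lists without control 2 or LGR5-ECD replicate 2 (up to 0.141 and 0.167). The tuft cell set test turned to higher in LGR5-ECD without control 2 (adjusted p = 0.000329).

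Both treatments were also compared with each other through the shared control. Lgr5 and the stem cell marker Phlda1 were the only 2 genes called higher in Rspo1 and lower in LGR5-ECD, and Ace, Ces2e, Krt20 and St3gal4 the 4 called lower in Rspo1 and higher in LGR5-ECD. Independent lists would share 0.21 and 0.29 genes. Calls in the same direction were more frequent, with 18 genes higher in both and 4 lower in both. Independent lists would share 0.34 and 0.18, and 20 simulations of unchanged groups with the same controls gave means of 0.05 and 0.05. Independent lists ignore the shared controls, and unchanged groups leave few calls to share. Neither figure therefore tells how much the controls added to the 18 and 4 shared calls. None of these shared calls was left without control 2, where limma called 0 genes in LGR5-ECD against Fc (571 higher and 659 lower at an unadjusted p under 0.05), and without LGR5-ECD replicate 2 that comparison called 4 higher and 0 lower. The log2 changes of LGR5-ECD against Fc kept their direction over the fits without 1 library, from -2.86 to -2.01 for Lgr5, 1.17 to 1.43 for Krt20 and 2.30 to 3.30 for Fos. The 18 included the Paneth cell genes Ang4, Clps, Defa21, Defa22, Defa26, Mmp7 and Mptx2 and the immediate early genes Atf3, Egr1 and Fos. The 4 were Nanos3, Rasa4 and a pair of unnamed transcripts; Ces2e, Nanos3 and Rasa4 were named after their values were seen. Across genes, the covariance of both sets of log2 changes was 0.134 (r = 0.393), against 0.074 (SD 0.0022; r = 0.601) in 100 simulations with the fitted spread and 0.116 from the difference between the 2 controls alone. With a pseudocount of 0.1 it was 0.288, against 0.201 in simulations on that scale, which were added later. In a check chosen after these values were seen, each comparison was given a control of its own. The covariance was then 0.049 with control 1 for Rspo1 and control 2 for LGR5-ECD, and 0.006 the other way round, so most of the 0.134 came from the shared controls. The mean of both, 0.028, is fixed by the 0.134 and the spread between the 2 controls, so this is no separate evidence.

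**Figure D3:**
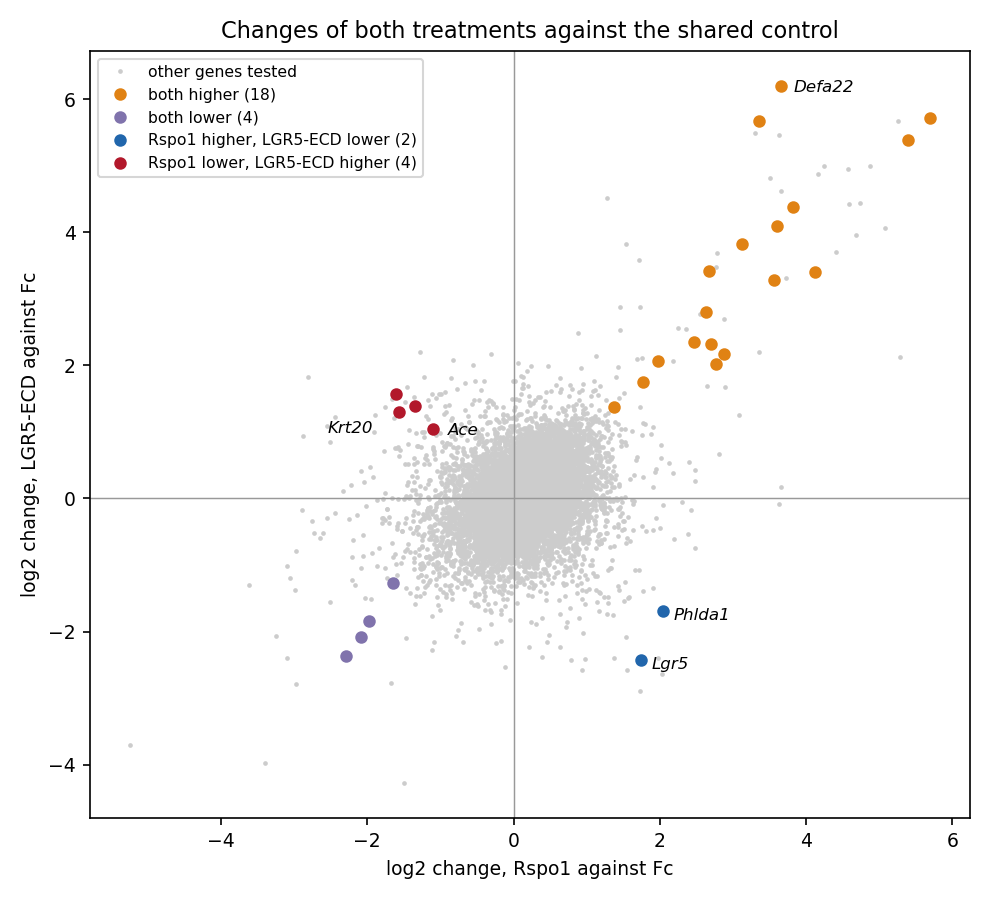
Log2 change on the log2(FPKM + 1) scale of each of the 11454 genes in Rspo1 against Fc (horizontal) and in LGR5-ECD against Fc (vertical), with genes called in both comparisons coloured by direction. The 18 genes higher in both lie at the upper right and the 4 lower in both at the lower left, while Lgr5 and Phlda1 lie at the lower right and Ace, Ces2e, Krt20 and St3gal4 at the upper left.

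For the genes called between Rspo1 and LGR5-ECD, the control mean lay between the treated means for 498 of 563 higher genes (88.5%) and 322 of 405 lower genes (79.5%). On a scale from 0 at the LGR5-ECD mean to 1 at the Rspo1 mean, the control stood at a median of 0.46 for the higher and 0.49 for the lower genes. This is a description without a test.

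Over all 3 comparisons, 40 of 63 camera tests passed the threshold, and 4 of these held with an estimated correlation. They were the enterocyte list in each comparison and the interferon list in Rspo1 against the control. The estimated correlation was 0.24 for the interferon list. It was -0.01 for the enterocyte list, below the preset 0.01, so the enterocyte calls held without any allowance for correlated genes. Even so, the camera adjusted p of that list in Rspo1 against LGR5-ECD went from 3.73e-28 to 0.000895. The estimated form also uses only the 5 residual degrees of freedom. The 36 lost calls therefore cannot be put down to correlated genes alone.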

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

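The result with Clca1 in the goblet list, the split of the controls and the simulations on other scales were chosen after the values were seen. All other alternatives were chosen before the data were examined. The cause of the differences below was not tested. The numbers of genes higher and lower in Rspo1 against Fc, 77 and 66, became 33 and 41 with a pseudocount of 0.1, 7 and 22 without a filter, and 42 and 43 with robust eBayes without trend. Quantile normalization gave 120 and 173, median-ratio scaling 126 lower genes, and a fit of only these 2 groups 129 higher genes. Leaving out 1 library gave 8 to 362 higher and 13 to 94 lower genes, the extremes coming without Rspo1 replicate 2 and control 1 for the higher, and control 2 and control 1 for the lower. For LGR5-ECD against Fc, 51 and 31 became 10 and 2 with a pseudocount of 0.1, 0 and 4 without a filter in limma (1266 and 935 at an unadjusted p under 0.05), 18 and 12 without trend, and 4 and 0 with only these 2 groups (838 and 474 unadjusted). Lower genes numbered 49 with median-ratio scaling and 56 with quantile normalization, and 0 to 153 higher and 0 to 49 lower genes were called without 1 library. Without control 2 both counts were 0 in limma (571 and 659 unadjusted), and without LGR5-ECD replicate 2 the lower count was 0 (885 unadjusted). For Rspo1 against LGR5-ECD, 563 and 405 became 212 to 467 and 183 to 380 without 1 library. The covariance of both changes, 0.134, was 0.288 with a pseudocount of 0.1 and 0.142 after quantile normalization, against 0.201 and 0.066 in simulations on those scales. With the controls split, 1 to each comparison, it was 0.049 and 0.006, against 0 in simulations.

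With the replicate block, Rspo1 against LGR5-ECD gave 319 higher and 267 lower genes and the same 16 set test calls. Libraries with the same number had correlations of their deviations of -0.019, -0.023 and -0.048 across genes, against -0.039 to 0.06 for different numbers. The values thus gave no sign of pairing by number, but they cannot show that such libraries were handled apart. No paired analysis was possible because the control columns carry no number from the labels, for the comparisons with Fc, where the replicate block was not run. The alternatives for GFP-positive against GFP-negative Fc cells and for the sort signature were not run either.

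Without 1 library the tuft cell list in LGR5-ECD against Fc had a mean relative to all genes from -1.187 (without control 1) to 0.517 (without control 2). Among named genes the direction changed only in results that were not called. Muc2 in Rspo1 against Fc ranged from -0.723 to 0.112 (0.047 without Rspo1 replicate 3). In LGR5-ECD against Fc, Smoc2 ranged from -0.549 to 0.346 (0.087 without LGR5-ECD replicate 3) and Dclk1 from -0.322 to 1.266. The median of the called ribosomal protein list in Rspo1 against Fc also changed sign after quantile normalization, as given above. Of 150 calls of named genes, 118 held without trend, 117 with only 2 groups, 144 with median-ratio scaling, 148 with quantile normalization, 71 without a filter and 104 with a pseudocount of 0.1. All 40 set test calls held with that pseudocount and with a filter at 5 FPKM, and 38 held after quantile normalization, where the ribosomal protein list in Rspo1 against Fc and the epithelial list in LGR5-ECD against Fc were lost. With Clca1 in place of Clca3, 1 goblet marker rose and 7 fell in Rspo1 against LGR5-ECD (camera adjusted p = 2.11e-05), 5 rose and 0 fell in LGR5-ECD against Fc (1.51e-07), and 3 rose and 0 fell in Rspo1 against Fc (0.275). These set tests used the preset correlation only. With Clca3 the goblet calls were lost under an estimated correlation. In the simulations under 30% of changes of 1 on the log2 scale were recovered, so changes of that size could be missed.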

Other observations

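All tests of explanations below were chosen after the results they bear on had been seen, and the genes of the next paragraph were chosen after their values were seen. The immune test first used the median marker, which was 0, and was changed to the mean after that was seen, and the set of short genes was narrowed after a first look at a wider set.

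The genes of this paragraph are single genes and no set was tested. Rnase1, a secreted ribonuclease, stood at 180 to 348 FPKM in Rspo1, 19.3 to 23.3 FPKM in LGR5-ECD and 11.2 and 29.3 FPKM in the controls. Rnase4 was at 115 ± 20.5 FPKM in Rspo1 (SD, n = 3) and 22.5 ± 3.32 FPKM in LGR5-ECD (SD, n = 3; log2 change 2.29, SE 0.26, limma adjusted p = 0.000636), and against the controls it changed by 1.81 (SE 0.29, adjusted p = 0.0203). Ang, of the same gene family, rose by 2.59 against LGR5-ECD (SE 0.58, adjusted p = 0.0204) and missed the threshold against the controls (adjusted p = 0.0970). Ang4, a further member, did not pass between the treated groups (-0.50, adjusted p = 0.661). Members of this family share sequence, so the division of reads among them is uncertain. In Rspo1 against LGR5-ECD the log2 changes were -3.48 for Slc51a (SE 0.37), -1.85 for Slc51b (SE 0.36) and -2.71 for Fabp6 (SE 0.46), 3 genes of bile acid handling, at adjusted p of at most 0.0116. Of these, Slc51a was higher in LGR5-ECD than in the controls (2.21, SE 0.41, adjusted p = 0.0460), and Slc51b (0.09, adjusted p = 0.933) and Fabp6 (-0.18, adjusted p = 0.889) did not pass. In Rspo1 against the controls Fabp6 was lower (-2.89, SE 0.51, adjusted p = 0.029). There Slc51a (-1.27, adjusted p = 0.154) and Slc51b (-1.76, adjusted p = 0.0627) did not pass. Apol10a was at 10.6 ± 4.33 FPKM in LGR5-ECD (SD, n = 3), and in Rspo1 it was listed at 0.269, 0 and 0.487 FPKM (log2 change -3.15, SE 0.33, adjusted p = 0.000432). Against the controls it was lower in Rspo1 (-1.89, SE 0.37, adjusted p = 0.0400) and did not pass in LGR5-ECD (1.26, adjusted p = 0.144).

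Paneth cell markers were higher in both treated groups than in the controls, which differed from each other by a median of 2.21 over these markers. Library depth is argued against by 994 genes of matched level, whose larger median change was 0.22. Medians of at least 1.827 above the control in both treated groups without any 1 library bear on a response that follows the level of R-spondin signalling. They argue against such a response only as far as the 2 shared controls give the true control level. Paneth cells carried over in differing amounts, with an unchanged profile, could not be excluded: the SD of the markers' changes was 1.63 times their median standard error in Rspo1 and 2.79 times in LGR5-ECD, and only values above 2 in both would have excluded it. The sort for GFP was meant to leave out Paneth cells. Lyz1 and other Paneth transcripts were found in the sorted libraries all the same, so the sort by itself does not speak against carry-over. A hypothesis that stays open is that the sorts held different shares of Paneth cells. With 2 controls it cannot be told apart from a response to either virus.

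Interferon response genes were lower in Rspo1 than in both other groups. Immune cells in the control and LGR5-ECD sorts are argued against by a mean of 0.274 FPKM over 28 immune markers there. The interferon genes had a mean of 14.6 FPKM. Lyz2, also a Paneth marker, was left out, and 2 of the 28 had a mean of at least 1 FPKM. Ptprc, the general leukocyte marker, reached at most 0.416 FPKM in any library. The sort for GFP was also meant to remove immune cells. Fewer differentiated cells in the Rspo1 sort would put LGR5-ECD above the control, and its median interferon change was between -0.456 and -0.19 without each library in turn. This counts only as far as the 2 shared controls give the true control level. In Rspo1 against LGR5-ECD, which needs no control, interferon and enterocyte genes were both lower in Rspo1 (medians -1.17 and -1.24). Fewer differentiated cells therefore stay possible. The number of interferon genes that fell was 5 to 10 against Fc and 12 to 21 against LGR5-ECD without 1 library. A difference in the dose of virus or in the response to it may also account for the pattern and was not tested, nor was an effect of Rspo1 itself.

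Cytosolic ribosomal protein genes were higher in Rspo1 than in LGR5-ECD. Gene length is argued against by 79 other short abundant genes, whose median change was -0.005, and by a rank correlation of -0.005 between length and change across genes, with a length for 91.7% of them. The shallow library LGR5-ECD replicate 3 is argued against by a median relative to all genes of 0.572 without it. With all libraries the median was 0.746 for the list and 0.085 for all genes. After quantile normalization the list kept its set test call against LGR5-ECD but lost the one in Rspo1 against Fc. A hypothesis is that the difference lies in the cells, but reads shared with processed copies were not tested.

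Of the 10 splits of the 6 treated libraries into groups of 3, 1 called as many genes as the real one, which was the real split itself with 968 genes, and the highest of the others called 1. With 10 splits a share under 0.05 cannot be reached.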
